A study of Mus musculus with 6 samples.

How the data were processed

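RNA from sorted germinal centre B cells of 6 mice was measured, 3 in the WT group and 3 in the KO group, and the groups and replicate numbers were taken from the sample labels. The authors deposited 1 table of raw read counts per gene symbol with 1 column per mouse. Per the submitters' processing notes, CASAVA, STAR 2.5.2 and featureCounts 1.5.2 were used with the mouse genome build mm10. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The extract protocol in the labels says only that standard Illumina library preparation was used. The table lists 15861 genes, each with at least 1 count in at least 1 library. It holds 0 rows for immunoglobulin or T cell receptor genes and none for mitochondrially encoded genes, so these were not analysed here. No 2 libraries of a group looked like repeat counts of a single library. The chi-square value per degree of freedom, over genes with a summed count of at least 10, was 14.6 to 51.4 for pairs of the same group.

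Depth was 3.79, 5.52 and 3.39 M counts in WT and 12.3, 14.3 and 13.1 M counts in KO. A count of 1 was worth 0.181 to 0.295 CPM in the WT libraries and 0.0698 to 0.0811 CPM in the KO libraries. A count of 0 allows up to 3 counts, or 0.543 to 0.885 CPM in WT and 0.209 to 0.243 CPM in KO. Such floors and the intervals of ratios cover counting error only, since the reads carry no molecular identifiers known here.

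The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust glmQLFit and glmQLFTest, no covariates, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The filter left 10926 genes. Standard errors are those implied by the F statistic, and the common biological coefficient of variation was 30.8%. CPM values of single genes use TMM-scaled library sizes, and sums of cell type markers use the library totals. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, for lists with at least 5 tested members, and adjusted over those lists. Camera with an estimated correlation and fry were run beside it. A list mean in a library is the mean over members of log2 CPM (prior count 2) minus the mean of the WT libraries. No mouse with Cre and without floxed alleles was analysed here, so effects of Cre cannot be parted from those of the deletion.

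The groups, tests, gene lists and naming rule were fixed before the data were examined. The rule named 5 genes in any case, of which Kdm1a, Bcl6, Prdm1 and Irf4 are reported, and some genes within the rule are not reported here. It then named up to 8 genes per direction with the largest log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups, leaving out predicted genes, pseudogenes and receptor genes, filled up by adjusted p where fewer passed. For each list it named up to 4 members if the list passed and up to 2 otherwise, and more for markers of other cells. Genes named beyond it are said to be so where they appear.

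The gene tests edgeR, DESeq2 and limma-voom, with and without quality weights, were first run on simulated data with 200 genes changed by known amounts. Camera at the preset correlation was run only on a simulated list of 30 genes moved by 0.5 log2 units and on a list of 30 unmoved genes. That does not give its rate of false calls. Camera with an estimated correlation, fry and the replicate block were not tested on simulated data. At the depths and spread of KO against WT, over 10742 genes, edgeR recovered 22.4% of genes changed 2-fold and 84.2% of those changed 4-fold, and 8.93% of its calls were unchanged genes. DESeq2 recovered 42.9% and 89.5% with 20.6% unchanged genes among its calls, and limma-voom 14.3% and 78.9% with 12.7%. With no simulated effect edgeR called 0 of 10745 genes. Simulated counts were drawn independently for each gene. These shares therefore leave out variation that genes share between libraries, which in the real data gave 259 calls in a split that mixed the genotypes.

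The alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in place of TMM, no filter, a stricter filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, each library left out in turn, and a 2-fold minimum. Thinning all libraries to the smallest total (11 draws, the draw with the median count) and removing a spline trend on transcript length and GC content were added after the data were seen. Lengths, GC content and coordinates came from a GENCODE vM21 annotation of the same build, in which 98.4% of the tested genes were matched by symbol.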

Results

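Polyadenylated RNA was sequenced from germinal centre B cells of mice, the B cells that mutate their antibody genes and compete for T cell help during an immune response. The cells had been sorted as B220+ GL7+ FAS+. The WT group held 3 libraries from mice with floxed Lsd1 alleles and no Cre, and the KO group held 3 libraries from mice with the same floxed alleles and a Cre allele that the labels call Cgamma-cre. The series design describes the animals as littermates, with 1 mouse per library. Lsd1 is the older name of Kdm1a, which encodes a histone demethylase that removes methyl groups from lysines 4 and 9 of histone H3 and acts in repressor complexes with CoREST. The WT libraries held 3786455, 5524852 and 3390805 counts, and the KO libraries held 12325300, 14327654 and 13127510. Mean depth was thus 4.23 ± 1.14 M counts in WT and 13.3 ± 1.01 M counts in KO (SD, n = 3 each). Every KO library was deeper than every WT library, by 3.13 times on average, so genotype and anything that set the depth cannot be told apart. Pairwise Pearson correlations of log2 CPM, across genes, ran from 0.934 to 0.964 within WT, from 0.936 to 0.964 within KO and from 0.906 to 0.96 between the groups. The first 2 principal components held 38% and 29.4% of the variance. On the first, the KO libraries had scores of -47, -26.5 and 17.7 and the WT libraries -17.6, 27.1 and 46.3, so it did not part the genotypes.

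The comparison asks which transcripts differ when germinal centre B cells carry the conditional Lsd1 deletion. Kdm1a itself (chromosome 4, 136550540 to 136602723 on the minus strand, mm10) was read at 134, 85.2 and 92.6 TMM-normalised CPM in WT and at 81.9, 33.0 and 21.8 in KO. The log2 fold change was -1.19 (SE 0.50), and the gene did not pass the test over all genes (edgeR quasi-likelihood test, adjusted p = 0.393). The library labelled KO 1 stood apart from the other two of its group. As a share of the library total its Kdm1a level was 87.5 CPM, within the WT range of 78.9 to 135, whereas on the TMM scale its 81.9 CPM lay below the lowest WT library at 85.2. On both scales it lay nearer to the lowest WT library than to the other KO libraries, which held 32.7 and 23.2 CPM of the library total. By neither scale does the target gene clearly bear out the label KO in that library. Without it the log2 fold change was -1.93 and passed (edgeR adjusted p = 0.017). The counts cover the whole gene, so reads from exons outside the floxed part are included. Each statement below on the KO group includes the library labelled KO 1.

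Among 10926 genes tested, 8 rose and 1 fell in KO against WT at an adjusted p under 0.05 (edgeR), all by at least 2-fold and without overlap between the groups. The clearest was Cxcr3, a chemokine receptor that guides lymphocytes towards interferon-induced ligands. It rose from 6.75 ± 1.11 CPM in WT to 59.1 ± 7.0 in KO (SD, n = 3), a log2 fold change of 3.11 (SE 0.25, edgeR adjusted p = 0.000414). Spata13, which encodes a guanine nucleotide exchange factor, rose by 2.23 on the log2 scale (SE 0.25, edgeR adjusted p = 0.00879). Zbtb32, a zinc finger transcriptional repressor, rose from 7.23 ± 1.70 to 28.0 ± 2.44 CPM (log2 fold change 1.96, SE 0.28). Vim, which encodes the intermediate filament vimentin, rose from 117 ± 24.2 to 324 ± 41.7 CPM (log2 fold change 1.47, SE 0.22). St8sia6, a sialyltransferase gene, rose by 2.24 (SE 0.32), and Abcb1b, which encodes a drug efflux pump, by 1.93 (SE 0.29). Pde2a, a cGMP-stimulated phosphodiesterase gene, was the 1 gene that fell, from 101 ± 21.3 CPM to 28.0 ± 5.95 (log2 fold change -1.85, SE 0.25, edgeR adjusted p = 0.0247). The remaining 2 genes lie outside the naming rule because of their low mean level and were named after their values were seen. Atp8b4, a putative phospholipid flippase gene, rose by 3.36 (SE 0.51). Clgn, which encodes calmegin, an endoplasmic reticulum chaperone of the testis, had 2 counts over the 3 WT libraries, all in WT 1, and 541 over the KO libraries. Its ratio of pooled CPM was 79.4, with a 95% interval of 21.9 to 657 that covers counting error only. The size of this ratio rests on WT 1, since the log2 fold change was 6.18 with all libraries and 10 without WT 1. St8sia6 and Abcb1b overlap exons of unnamed genes on the other strand and Pde2a overlaps one on its own strand, and reads of Abcb1b can also be shared with its close paralogue Abcb1a. Their counts are therefore less certain.

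**Figure D1:**
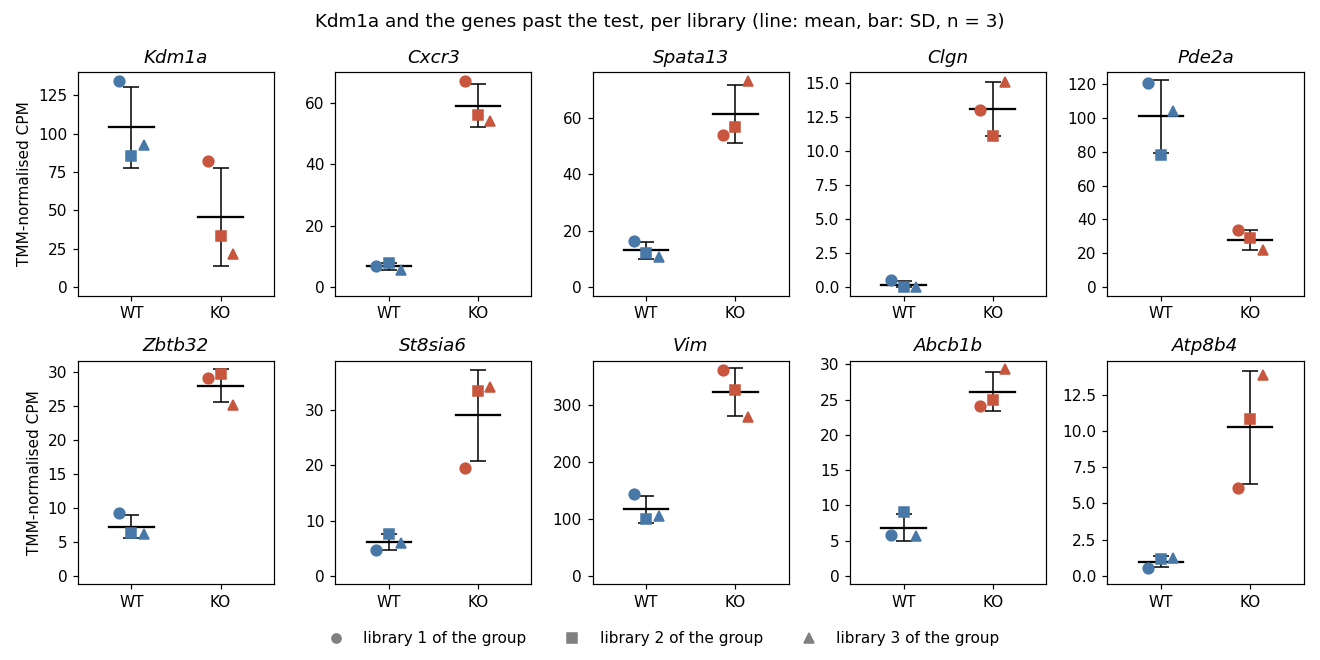
TMM-normalised CPM (vertical axes) of Kdm1a and of the 9 genes that passed the edgeR test, for the 3 WT and 3 KO libraries. Points are single libraries, lines the group means and bars the SD (n = 3). Kdm1a reached 81.9 CPM in the library labelled KO 1, against 33.0 and 21.8 in the other KO libraries and 85.2 in the lowest WT library. The groups did not overlap for Kdm1a, by this narrow gap, or for any of the 9 genes.

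Cxcr3 passed in all 6 fits that left out 1 library, at an adjusted p of at most 0.021 in edgeR and its alternatives. Spata13 and Clgn passed in 4 of those 6 fits, St8sia6, Zbtb32 and Pde2a in 3, and Vim, Abcb1b and Atp8b4 in 2. The count of genes was 11 without WT 1, 1 without WT 2, 1 without WT 3, 24 without KO 1, 3 without KO 2 and 18 without KO 3. By limma-voom 2 genes passed, Cxcr3 and Clgn, and by DESeq2 122 passed, among them all 9. In simulated data of the same depths and spread, genes were drawn independently. There edgeR recovered 22.4% of genes changed 2-fold and 84.2% of genes changed 4-fold, so most changes of 2-fold or less were not detectable with these libraries. At an unadjusted p under 0.05, 776 genes were higher and 601 lower in KO (edgeR). The groups did not overlap for 1965 genes, or 18% against 10% by chance. Genes vary together across these libraries, and the share in other splits was not examined. The excess can therefore not be tied to the genotype. Of genes that missed the threshold, Cdh17, a cadherin gene, had a log2 fold change of 2.57 (SE 0.38, edgeR adjusted p = 0.0561) and L3mbtl3, which encodes a reader of methylated lysine, one of 1.74 (SE 0.29). They passed in 10 and 6 of 17 alternatives. Shisa8 (-1.75, SE 0.28, edgeR adjusted p = 0.0504), the linker histone gene H1fx (-1.28, SE 0.23), Gcat (-1.22, SE 0.23) and Coro1c (-1.11, SE 0.21) had the next values on the other side, and passed in 8, 3, 3 and 4 of the 17.

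Lists of genes that mark other stages of the B cell lineage leaned higher in KO, a result of 1 of 3 list tests. Of 32 gene lists, 27 had at least 5 tested members and 12 passed camera with a preset correlation of 0.01, 8 higher and 4 lower. With an estimated correlation none of the 27 passed, and the adjusted p of the 12 lists lay between 0.58 and 0.69. By fry, which asks only whether a list's own genes move one way, none passed either, with adjusted p from 0.072 to 0.6. The memory B cell list had the largest median log2 fold change, 1.25, with 23 of 24 members above 0 (camera adjusted p = 5.4e-08, and adjusted p = 0.58 with an estimated correlation). Of its members 2 passed over all genes, Zbtb32 and Vim, and 10 passed when adjusted over the list alone. Cd80, a costimulatory ligand gene, had a log2 fold change of 1.71 (SE 0.37) and Hhex, a transcription factor gene of memory B cell formation, 1.40 (SE 0.37). The members averaged 1.76 log2 units above the WT mean in the library labelled KO 1 and 0.77 and 0.76 in the other KO libraries, against a range of 0.11 among the WT libraries. Without KO 1 the median was 0.56, and camera still passed (adjusted p = 2e-08). The list shares 13 members with other lists.

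The follicular naive B cell list had a median of 0.61, with 15 of 16 members above 0 (camera adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation). S1pr1, a receptor for lymphocyte egress, had a log2 fold change of 1.21 (SE 0.40), but 0.562 without KO 1, and Il4ra, the interleukin 4 receptor chain, one of -0.95 (SE 0.22). None of the 16 passed over all genes, and the 1 member that passed over the list alone was lower. List means were 0.99 log2 units above WT in the library labelled KO 1 and 0.50 and 0.25 in the others. The call was lost without WT 2 (median 0.91, camera adjusted p = 0.061). The plasma cell list had a median of 0.37, with 18 of 23 members above 0 (camera adjusted p = 0.0088, and adjusted p = 0.66 with an estimated correlation), and no member passed over all genes or over the list alone. Prdm1, the regulator of plasma cell differentiation, was read at 26.9, 3.18 and 14.3 CPM in KO and 4.20, 3.13 and 1.56 in WT (log2 fold change 2.30, SE 0.77, edgeR adjusted p = 0.305). Irf4, a transcription factor gene of the same step, had a log2 fold change of 1.10 (SE 0.29, edgeR adjusted p = 0.213). The plasma cell call was lost without WT 1 (camera adjusted p = 0.053) and without WT 2 (0.12), and also with the stricter filter (median 0.17, 0.087) and with quality weights (0.066).

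Genes repressed by BCL6, the transcription factor that maintains germinal centre B cells, had a median log2 fold change of 0.37, with 22 of 29 members above 0 (camera adjusted p = 0.006, and adjusted p = 0.66 with an estimated correlation). No member passed over all genes and 5 passed over the list alone. Bcl2, an inhibitor of apoptosis, was read at 23.5, 5.43 and 4.86 CPM in KO and 1.56 to 2.49 in WT. The list's median was 0.18 without KO 1, where it still passed, and 0.69 without WT 2, where it did not (camera adjusted p = 0.095). Of its members 22 belong to other lists as well. Bcl6 itself had a log2 fold change of -0.04 (SE 0.22) and did not pass. The germinal centre identity list (median -0.09, camera adjusted p = 0.34), the dark zone list (median -0.08, 0.63) and the light zone and CD40 response list (median 0.20, 0.056) did not pass either. The light zone list passed in 7 of 17 alternatives, among them the fits without WT 3 (camera adjusted p = 0.0037) and without KO 2 (0.0045) and the fit with a length and GC trend removed (median 0.35, 0.0034), but not with an estimated correlation (0.69).

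Migration and chemokine receptor genes had a median of 0.36, with 16 of 23 members above 0 (camera adjusted p = 0.0085, and adjusted p = 0.58 with an estimated correlation). Cxcr3 passed over all genes and 6 members passed over the list alone. The integrin genes Itga4 and Itgb7 had log2 fold changes of 1.25 (SE 0.29) and 1.07 (SE 0.33). The median was 0.18 without KO 1, with the call kept (camera adjusted p = 0.0012), 0.24 without KO 3 and 0.61 without WT 3, and the call was lost without WT 2 (0.19) and with quality weights (0.11). The type I interferon response list had a median of 0.38, with 24 of 30 members above 0 (camera adjusted p = 0.00035, and adjusted p = 0.66 with an estimated correlation). None of its members passed over all genes and 5 did over the list alone. Ifit2 had a log2 fold change of 1.55 (SE 0.34) and Gbp3 one of 1.15 (SE 0.29), genes of families with close paralogues. The call was lost without WT 1 (camera adjusted p = 0.066), and the median was 0.59 without WT 3 and 0.62 without KO 2. For interferon gamma and MHC class I genes the median was 0.34 (camera adjusted p = 0.025, and adjusted p = 0.69 with an estimated correlation), but 0.06 without KO 1 (camera adjusted p = 0.46). This call was also lost without WT 1 (0.066), without WT 2 (median 0.69, 0.43), with the stricter filter (median 0.22, 0.052) and with quality weights (0.38), and the median was 0.59 without WT 3 and 0.64 without KO 2. Chromatin and histone modifier genes had a median of 0.28 (camera adjusted p = 0.046, and adjusted p = 0.69 with an estimated correlation), 0.07 without KO 1, 0.12 without WT 3 and 0.42 without KO 2. That call was lost in 4 of the 6 fits that left out 1 library, namely without WT 2 (0.24), WT 3 (0.17), KO 1 (0.63) and KO 3 (0.091), and also with DESeq2 size factors (0.051), with the stricter filter (0.057), after thinning to equal depth (median 0.16, 0.13) and once a length and GC trend was removed (median 0.05, 0.27). For the 2 interferon lists and the chromatin list, the mean in KO 2 lay within the range of the WT libraries.

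**Figure D2:**
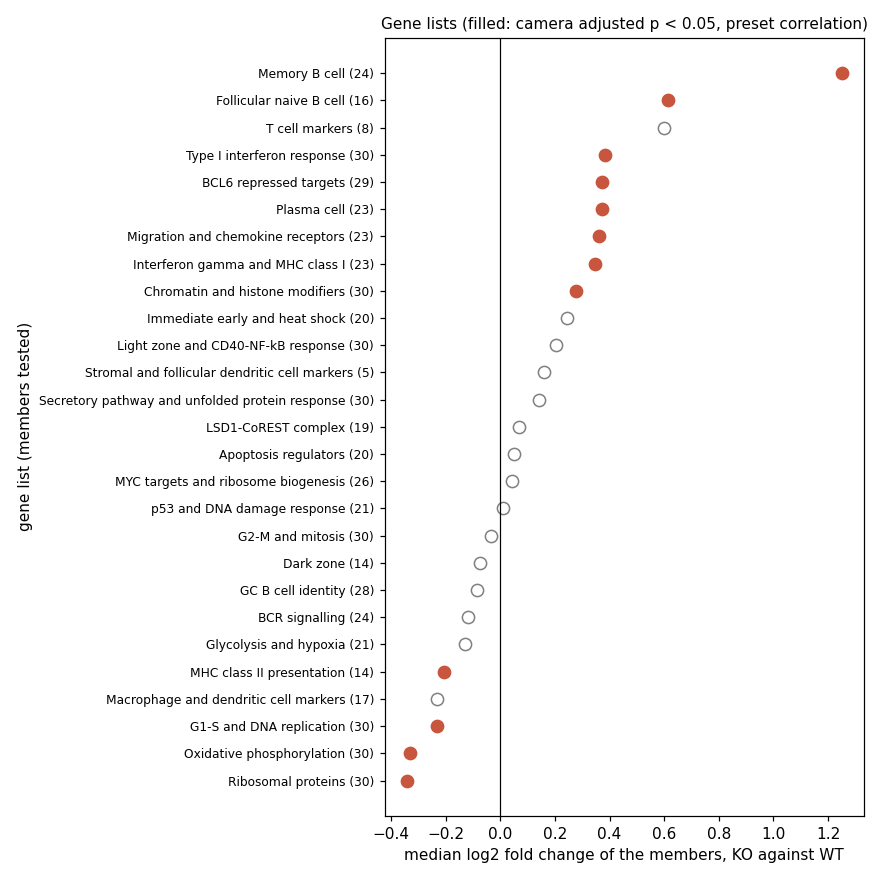
Median log2 fold change of KO against WT (horizontal axis) for the 27 gene lists tested, with the number of tested members in brackets. Filled points are the 12 lists with a camera adjusted p under 0.05 at a preset correlation, from -0.34 for ribosomal proteins to 1.25 for memory B cell genes.

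Lists of translation, respiration and DNA replication genes leaned lower in KO by small amounts, again by the preset test and not by the other 2. Ribosomal protein genes had a median log2 fold change of -0.34, with 29 of 30 members below 0 (camera adjusted p = 1.6e-06, and adjusted p = 0.66 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.33, with 28 of 30 below 0 (camera adjusted p = 1.6e-06, and adjusted p = 0.66 with an estimated correlation). The DNA replication list had a median of -0.23, with 28 of 30 below 0 (camera adjusted p = 0.00065, and adjusted p = 0.66 with an estimated correlation). Over 17 alternatives its median ran from -0.285 to -0.123. No member of these 3 lists passed over all genes or over the list alone. Cox4i1, a subunit of cytochrome c oxidase, had a log2 fold change of -0.85 (SE 0.27), Rps14 one of -0.78 (SE 0.29) and the replicative helicase subunit gene Mcm5 one of -0.69 (SE 0.23). Over 17 alternatives Cox4i1 ran from -1.11 to -0.403, Rps14 from -1.1 to -0.414 and Mcm5 from -0.877 to -0.533. Ribosomal protein genes have many processed pseudogenes, to which some of their reads could be assigned. Their means relative to WT were -0.47 in the library labelled KO 1, 0.03 in KO 2 and -0.63 in KO 3, and those of the oxidative phosphorylation genes were -0.42, -0.02 and -0.59, so KO 2 lay within the WT range for both. Without KO 2 the median was -0.58 for ribosomal proteins and -0.55 for oxidative phosphorylation, and without KO 3 it was -0.21 for oxidative phosphorylation. Once a trend on transcript length and GC content was removed from each library, the medians were -0.09 for ribosomal proteins (camera adjusted p = 0.024) and -0.16 for oxidative phosphorylation (0.001). MHC class II presentation genes had a median of -0.21, with 11 of 14 below 0 (camera adjusted p = 0.02, and adjusted p = 0.66 with an estimated correlation). H2-Ab1 had a log2 fold change of -0.61 (SE 0.23), which ran from -0.801 to -0.219 over 17 alternatives. The median of the MHC class II list was -0.31 without WT 1. The call was lost without WT 2 (camera adjusted p = 0.061) and without WT 3 (median -0.09, 0.13), and likewise with no filter (0.11) and once the length and GC trend was removed (median -0.09, 0.34).

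Macrophage transcripts varied widely between libraries of both genotypes. The 20 macrophage and dendritic cell markers summed to 991, 1760 and 3240 CPM of the library total in WT and to 959, 918 and 3810 in KO. C1qb, a complement gene of macrophages, ranged from 15.8 CPM in KO 1 to 398 in WT 3. The list did not pass with all libraries (median -0.23, camera adjusted p = 0.35) but did without KO 3 (median -2.78, camera adjusted p = 3.9e-07) and without WT 1 (median -0.52, 0.0041). T cell markers summed to 148, 165 and 190 CPM in WT and 182, 186 and 141 in KO, most of it Cd2, and the list did not pass (camera adjusted p = 0.45). Cd3d and Cd3g had at most 15 counts in any library and Cd4 at most 152. The genes of the LSD1 and CoREST complex did not pass as a list (median 0.07, camera adjusted p = 0.96), and Gfi1, a repressor that recruits it, had a log2 fold change of 1.72 (SE 0.43, edgeR adjusted p = 0.195).

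**Figure D3:**
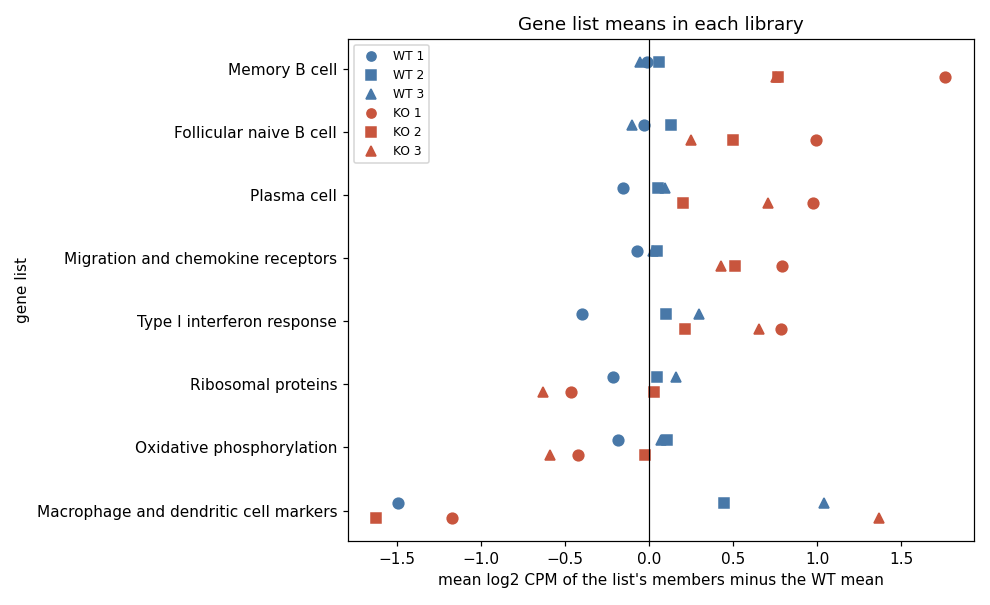
Mean log2 CPM of the members of 8 gene lists in each library, minus the mean of the WT libraries (horizontal axis), with 1 point per library. Memory B cell genes lay 1.76 log2 units above the WT mean in the library labelled KO 1 and 0.77 and 0.76 in the other KO libraries, whereas macrophage markers ran from -1.62 to 1.37 across the KO libraries.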

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

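Thinning to equal depth and removal of a length and GC trend were chosen after the data were seen. The 9 called genes kept their direction in every fit run. Of 17 alternatives, Cxcr3 passed in 17, Clgn in 15, Spata13 in 14, Zbtb32 and Pde2a in 13, Vim in 12, St8sia6 and Abcb1b in 11 and Atp8b4 in 10. The count of 9 genes became 10 with DESeq2 size factors, 12 with upper-quartile scaling, 13 with the stricter filter and 9 with a 2-fold minimum. It became 18 with library size alone, 93 with no filter, 122 with DESeq2, 2 with limma-voom, 18 with quality weights, 15 after thinning (8 to 19 over the 11 draws) and 16 after removal of the length and GC trend. It ran from 1 to 24 when 1 library was left out. The cause was not tested, except that fits without a library rest on fewer samples and the fit with no filter tested 15861 genes. Library size alone moved the median log2 fold change of all genes from 0.01 to 0.13. The library totals of WT, 3390805 to 5524852 counts, limit the detection of genes with few counts.

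The Kdm1a log2 fold change stayed below 0 in all 17 alternatives. It ran from -1.93 without KO 1 to -0.878 without KO 3, and passed in 1 alternative, the fit without KO 1 (adjusted p over all 17 from 0.017 to 0.95). The count of 12 lists was 0 with an estimated correlation (1 list at an unadjusted p under 0.05) and 0 by fry (3 at an unadjusted p under 0.05). It ran from 5 to 13 when 1 library was left out and from 9 to 15 under the remaining alternatives. Of the lists that did not pass, the light zone list did in 7 of 17 alternatives, immediate early genes in 5, macrophage markers in 3, the secretory list in 1 and T cell markers in 1 of 15. No called list changed direction. The memory, follicular naive, BCL6 target, type I interferon, DNA replication, oxidative phosphorylation and ribosomal protein lists passed in all 9 fits with another scaling, filter, weighting, block, depth or trend. The chromatin list passed in 5 of these 9, the plasma cell, interferon gamma and MHC class II lists in 7 and the migration list in 8, and the report names the settings that ended these calls. Camera works on limma-voom values already, so limma-voom was no separate alternative for lists. The alternative without immunoglobulin and T cell receptor genes was not run, since the table holds 0 of them.

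The replicate numbers did not pair the libraries. Deviations from the group means correlated at 0.34, -0.052 and 0.44 for libraries 1, 2 and 3, across genes, and 1 and 3 correlated best with their own number. With the replicate block 21 genes and 15 lists passed, among the genes Cdh17 (adjusted p = 0.018, over all alternatives from 1e-08 to 0.36) and L3mbtl3 (0.036, from 0.00094 to 0.36).

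Among results in these texts, the following did not pass and changed direction, with the cause not tested. Bcl6 was at 0.0742 with library size alone, 0.101 with quality weights, and from -0.16 to 0.138 with 1 library left out, as Clu was from -3.84 to 1.01. List direction is that of camera, which can differ from the sign of the median. The dark zone median was -0.0723 with no filter and -0.00146 with quality weights, the mitosis median -0.0326 with no filter, the CoREST complex median 0.0662 with the block, and the MYC target median 0.00668 with quality weights. The stromal median was 0.318 with library size alone, 0.57 with no filter and -0.406 with the block. With 1 library left out, medians ran from -0.101 to 0.153 for mitosis, 0.13 to 0.467 for immediate early genes, -0.0222 to 0.126 for the CoREST complex, -0.0306 to 0.0977 for MYC targets, -2.78 to 0.195 for macrophage markers and -0.0141 to 1.03 for T cell markers.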

Other observations

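The tests on the library labelled KO 1 were chosen after the results they concern had been seen, and the T-bet list was drawn up after Cxcr3 had been seen. Genes linked to the transcription factor T-bet, which drives Cxcr3 in lymphocytes, were examined as a hypothesis of a wider T-bet associated programme. Of 17 such genes, with Cxcr3 left out, 11 were tested and 9 had a log2 fold change above 0, with a median of 1.36 (camera p = 0.0083, and p = 0.14 with an estimated correlation). None passed over all genes, the smallest edgeR adjusted p being 0.28. Tbx21, which encodes T-bet, was read at 7.62, 7.04 and 8.73 CPM in WT and at 66.4, 15.9 and 16.1 in KO, and Zeb2 at 4.73 to 10.4 in WT and 41.3, 11 and 20.1 in KO. These genes had the smallest p of the list, and the groups overlapped for every other tested member. Fcrl5, for example, was at 3.74 to 7.82 in WT and at 60.7, 8.4 and 6.5 in KO. When the library labelled KO 1 was left out the median was 0.40, with camera p = 0.0015 at the preset correlation. The list includes 2 macrophage markers and Fas, by which the cells were sorted. The preset test passed upward, which a T-bet associated programme would give. That test also called lists in each split that mixed the genotypes, so it cannot decide on such a programme. The test with an estimated correlation leaves it open, and depth was not parted from genotype.

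Germline genes were close to absent. Of 20 genes fixed as 2-cell-like or germline, 4 were in the table, and they summed to 0.264, 0.181 and 0.295 CPM in WT and 0.649, 0.698 and 0.914 in KO, most of it Ddx4 with 1 count in each WT and 8 in each KO library. Of the 27 lists tested, 15 did not pass, with camera adjusted p from 0.056 to 0.96. Among them were BCR signalling (median -0.12), the secretory pathway and unfolded protein response (0.14), p53 and DNA damage (0.01), apoptosis regulators (0.05), glycolysis and hypoxia (-0.13), MYC targets and ribosome biogenesis (0.04), mitosis (-0.04), and immediate early and heat shock genes (0.24, which passed in 5 of 17 alternatives, among them without WT 1 and without KO 3 at camera adjusted p of 0.011 and 0.02, and with a length and GC trend removed at a median of 0.45 and 0.024). For the dark zone and macrophage lists the mean lay above 0 while the median and the test lay below, and for the stromal list (median 0.16) the mean was -0.48. Clu, a gene of follicular dendritic cells, stood at 126 CPM in WT 1 and between 1.96 and 6.28 in the other libraries. Other members of its list were mixed in WT 1. Cxcl13 and Madcam1 had 0 counts there, while Sparc (4.23 CPM of the library total) and Mfge8 (7.13) were highest there. Neutrophil, erythroid and NK cell markers summed to 2.11 to 20.3 CPM in WT and 4.89 to 9.98 in KO. The immunoglobulin constant region and mitochondrially encoded lists had 0 members in the table, and the sex-linked list had 1 tested, Xist, with at least 765 counts in each library, while Uty had at most 1.

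Vim and St8sia6, both higher in KO, are neighbours on chromosome 2, with 68.2 kb between the end of the former at 13582826 and the start of the latter at 13651021. The other 2 tested genes within 500 kb of Vim, Trdmt1 (log2 fold change 0.69, SE 0.32) and Rsu1 (0.08, SE 0.24), did not pass. DNA around the Cre allele, taken from its name to lie at the immunoglobulin gamma genes, was examined as a source of strain differences. Within 5 Mb of Ighg1 on chromosome 12, 7 of 56 tested genes had an unadjusted p under 0.05, or 12.5% (exact 95% interval 5.18 to 24.1) against 12.6% elsewhere (one-sided Fisher's exact test, p = 0.57), which argues against a share 2 times as high there.

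With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. For genes, 2 of the 10 splits gave at least the 9 of the real one. The other was WT 1, KO 1 and KO 2 against WT 2, WT 3 and KO 3, with 259 genes, 256 of them higher in the latter. It points to a structure of the samples. The first principal component, with 38% of the variance, parted the libraries in the same way. Its scores were -17.6, -47 and -26.5 for WT 1, KO 1 and KO 2, and 27.1, 46.3 and 17.7 for WT 2, WT 3 and KO 3. No fit adjusted for macrophage transcripts. Among the 17 tested macrophage and dendritic cell markers 10 passed in that split, all higher in WT 2, WT 3 and KO 3, with a median log2 difference of 3.41. The levels of C1qa, for example, were 117, 301 and 240 CPM there and 24.3, 17.3 and 15.8 in the other three, although the sort on B220 would exclude most macrophages. For lists, 2 of the 10 splits gave at least the 12 of the real one, and the highest of the others gave 12. Each of the other splits, which mix the genotypes, called lists by the preset test, from 1 to 12. The number of list calls is therefore not particular to the genotype.

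The medians of the ribosomal protein and oxidative phosphorylation lists lay below 0, a call of the preset test that was lost with an estimated correlation (adjusted p = 0.66 for both) and by fry (0.43 for both). KO 2 lay within the WT range for both lists. Across genes, which are not independent replicates, the log2 fold change correlated with transcript length (Spearman correlation 0.37) and GC content (-0.37). After thinning to equal depth the median over both lists was -0.332 (SE 0.032), as at full depth. Thinning leaves the expected ratios of such abundant genes as they are, so this decides nothing, and depth cannot be told apart from genotype. Removal of the length and GC trend left -0.12 (SE 0.039), less than 0.5 of the uncorrected size. It lay beyond the 0.1 fixed as no change, but by less than its SE. These SEs, like those of the medians below, resample genes as if independent and do not measure the spread between mice. A length or GC bias may account for most of the difference, though a true change that follows these properties would be removed too. Whether a smaller change remains stays open. An effect of the genotype was not tested apart from these.

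The memory B cell list passed upward by the preset test but not with an estimated correlation (adjusted p = 0.58) or by fry (0.33), and 2 of its 24 members passed over all genes. Its mean was highest in the library labelled KO 1, as was that of each of the 8 lists called higher. The plasma cell mean, for example, was 0.98 there and 0.20 and 0.71 in the other KO libraries. For interferon gamma and MHC class I genes it was 1.07 against -0.03 and 0.45. The KO library with the highest Kdm1a level thus had the largest shift in every list called higher. Cells of another B cell state in the library labelled KO 1 alone could raise the memory list. Without it the median fell from 1.25 to 0.565 (SE 0.19), between the bounds set for and against this, so that part of the size cannot be told apart from such cells, while the other KO libraries still lay above WT. For the 9 called genes the median absolute log2 fold change was 2.23 with all libraries and 2.31 (SE 0.42) without KO 1. This decides nothing on such cells, since genes picked without overlap between the groups must differ in KO 2 and KO 3 as well.

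The Kdm1a level of the library labelled KO 1 lay in the WT range as a share of the library total (87.5 CPM against 78.9 to 135), but just below it on the TMM scale (81.9 against 85.2 to 134). If that library came from a mouse without Cre, genes called without it should lie nearer to WT there. Of the 24 such genes, Kdm1a was set aside, as was Arpp21, which was not tested with all libraries. Of the other 22, 17 lay closer to the other KO libraries (77.3%, exact 95% interval 54.6 to 92.2, which takes the genes as independent). The library labelled KO 1 shares the depth of the other KO libraries, so differences that came with depth would place it nearer to them too. The share therefore cannot decide on a mouse without Cre, and incomplete deletion stays open as well. Cells that had not deleted the gene are a candidate explanation. The follicular naive list bears only on such cells of another B cell state, not on germinal centre B cells that kept the gene. It stood 0.614 log2 units higher in this library than in the other KO libraries, against a WT range of 0.229. Cells of another B cell state would need this rise, but the genotype could give it as well.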
